A study of Homo sapiens with 4 samples.

How the data were processed

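Total RNA of A549 and SBC-3 cells, each transduced with a control or a SALL4 vector and taken after 24 h, was purified on silica columns, and cRNA labelled with Cy3 from a low RNA input was hybridised, per the labels' protocols. Each of the 4 groups had 1 array, and groups were taken from the sample titles. The deposited scanner files hold spot intensities from Agilent Feature Extraction 10.10.1.1, the version given in the submitters' processing notes. Per the file headers, the software subtracted the background with a spatial detrend, replaced very low spots by a small positive surrogate, and did not normalize between arrays. The intensity used was the processed signal, with the software's own error and its flags for outlier, saturated and well-above-background spots. The value table deposited for the series holds intensities too. It equals the processed signal times a constant per array (1.14, 1.18, 1.15 and 1.35 in the order A549 control, A549 SALL4, SBC-3 control, SBC-3 SALL4), on a linear scale and not centred per gene. The column medians in the same order were 189, 144, 122 and 132. The rule behind the constants stays unknown, and a direction does not apply to single intensities. The files place the 4 arrays on 1 slide, read in 1 scan.

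Each array had 58717 spots that are not controls, for 42405 probes. Spots well above background were 72.6% on the A549 control array, 64.6% on the A549 SALL4 array, 58.4% on the SBC-3 control array and 60.6% on the SBC-3 SALL4 array. No spot was saturated, and 406, 398, 389 and 363 outlier spots in the same order were left out. Probes were named by their transcript accession, without version, through a RefSeq gene table of assembly GRCh38.p14, used for names and not for coordinates because the array grid is of build hg19. A current symbol was found for 26364 probes (62.2%), and 16041 stayed unnamed. The named probes stand for 19796 genes, of which 5152 have more than 1 probe. For 999 probes spotted 10 times, the median standard deviation between spots of an array was 0.0676, 0.0686, 0.0618 and 0.0670 on the log2 scale, over those well above background.

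The log2 of the processed signal minus the array's 75th percentile was used throughout, computed in R 4.3.3 with the data.table package, version 1.17.8. Spots of a probe were averaged on the log2 scale. A gene was represented by its probe with the highest mean over the 4 arrays, and probes that disagree are named beside the gene. Within a line, a gene entered when well above background on at least 1 of its 2 arrays. Where it was so on 1 array alone, the difference is a bound against the higher of that dim array's lowest signal among probes well above background and the gene's own value. Genes at or past 2-fold were counted, with no p-value because there is no replicate. Bright genes are those whose brighter array is at or above the median of that array's genes well above background. In the fits over all arrays they are those whose mean over the 4 arrays is at or above the median of the genes.

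Over both lines, limma 3.58.1 (lmFit and eBayes) was fitted with line and vector as additive terms on genes well above background on at least 2 of the 4 arrays, with a Benjamini-Hochberg adjusted p under 0.05 as threshold, two-sided. The 2 lines act as the pairs of the vector contrast, since each line has its own control. Differences between lines that rest on genes not well above background on any array, or on 1 of the 2 arrays, of 1 line are given as bounds in the same way. The fit was tested on simulated data made from 14626 genes in 5 simulations, each with 50 genes changed at each of 4 sizes, and gave a mean of 1.8 false calls.

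The 25 gene lists covered pluripotency, SALL4 partners, drug efflux, NRF2 detoxification, platinum response and repair, tubulins, apoptosis, p53, cell cycle, stem cell markers, epithelial to mesenchymal transition, Wnt, interferon, NF-kB, stress responses, immediate early genes, hypoxia, lipid synthesis, histones, lung and neuroendocrine markers, and markers of fibroblasts, blood cells and endothelium. They were written before the data were examined, as were the naming rule and most alternatives. Per line, a list's median was placed among 10000 random lists of the same size, matched over 20 signal bins. Over all 4 arrays camera was run with a preset correlation of 0.01 and with an estimated one, and fry on the same fit. Named genes are SALL4, then the 10 highest and 10 lowest bright genes with an official symbol per line. The 10 highest and 10 lowest by the smaller of both lines' differences follow, among genes bright in both. Between the lines, they are the 10 genes furthest higher in each line by the fitted difference, among genes past the test. For a list, up to 4 members at or past 2-fold were named, or else the furthest member, and further list members were named after their values were seen. No bright gene was at least 2-fold different in opposite directions.

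Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter and a stricter filter on dim probes, the mean over a gene's probes, the deposited value table, a trended robust variance prior, a fit without the line term and each line alone. Normexp used the median spot and background signals, because the files as given hold no mean signal. Cyclic loess, bright genes alone and the line fit without the A549 control array were added after seeing the data. The slide was not used as a block, there being 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.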

Results

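RNA of 2 established human lung cancer lines was measured on 4 Agilent 1-colour (Cy3) expression arrays. A549 is a line from a lung adenocarcinoma and SBC-3 a line from a small cell lung carcinoma. Cells of each line received either an empty pCMV6 vector, called the control vector here, or a pCMV6 vector carrying SALL4, and RNA was taken 24 h later. SALL4 encodes a zinc finger transcription factor of embryonic stem cells. The 4 groups (A549 control vector, A549 SALL4 vector, SBC-3 control vector and SBC-3 SALL4 vector) held 1 array each. The study asked whether SALL4 acts as a drug resistance factor in lung cancer, and the arrays show which RNAs differed once it was supplied. Of 19796 genes with a current symbol, 15419 were well above background on the A549 control array, 14087 on the A549 SALL4 array, 13022 on the SBC-3 control array and 13348 on the SBC-3 SALL4 array. No spot was saturated. The errors given for single genes come from the scanner software's model of spot noise. They are not replicate errors, because no group was repeated, and the number of arrays limits the precision of every value.

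SALL4 was higher on both arrays of cells given its vector. The SALL4 probe (NM_020436), spotted in duplicate, read a mean signal of 222 on the A549 control array and 1954 on the A549 SALL4 array. After scaling this was a log2 difference of 3.21 ± 0.21, or 9.25-fold. In SBC-3 the probe read 519 with the control vector and 16173 with the SALL4 vector, a log2 difference of 5.17 ± 0.21 or 36.1-fold. The normalized log2 level of SALL4 with its vector was 0.49 in A549 and 3.76 in SBC-3.

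The first comparison set the SALL4 vector against the control vector in A549. Besides SALL4, the bright A549 genes highest with the SALL4 vector were led by a probe of CSH1, the placental lactogen gene. It read 26.0-fold higher (log2 4.70 ± 0.22). The other CSH1 probe differed by 0.31 on the log2 scale and was well above background on the SALL4 array alone. SBSN, the epidermal protein suprabasin, was 3.24-fold higher (log2 1.70 ± 0.21). NT5E, the cell surface enzyme CD73 that makes adenosine, was 1.74-fold higher, with a log2 difference of 0.80 on its brighter probe and 0.29 on the other. The secreted Wnt antagonist SFRP1 was 1.56-fold higher and FST, the activin-binding follistatin, 1.55-fold higher. LY6K was 1.68-fold, RNF182 1.58-fold and the galanin receptor gene GALR3 1.53-fold higher. HMGA2, a chromatin architectural protein of embryonic and cancer cells, was 1.41-fold higher, with log2 differences of 0.50, 0.42 and -0.01 on its 3 probes. NSA2 was higher by 0.98 on the log2 scale on 1 probe and by 0.04 on its other probe.

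Among the bright A549 genes lower with the SALL4 vector, EGR1, an immediate early transcription factor, was 1.85-fold lower (log2 -0.89 ± 0.20). CHAC1, which degrades glutathione and is induced by amino acid and endoplasmic reticulum stress, was 1.93-fold lower, with log2 differences of -0.95 and -0.75 on its 2 probes. The thrombospondin gene THBS3 was 2.14-fold lower. The adhesion protein gene CNTN1 was lower by 0.99 on its brighter probe (log2 -0.99) and showed a log2 difference of -0.25 on the other. The largest differences came from 6 genes each read from 1 spot. The zinc finger gene ZNF677 was at least 30.8-fold lower and the olfactory receptor gene OR5K4 at least 27.5-fold lower, both not well above background on the SALL4 array. The homeobox gene DBX1 was 14.9-fold, ZNF181 9.31-fold, TMEM229B 6.54-fold and the long non-coding RNA LINC00261 6.08-fold lower. "At least" marks a bound, taken from the bright array's value and the higher of the dim array's detection floor and the probe's own value there.

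Of the 15686 A549 genes compared, 45 were at least 2-fold higher with the SALL4 vector and 1251 at least 2-fold lower. Of these, 31 of the higher and 927 of the lower genes were bounds. Most of the lower genes were dim. The 13820 genes measured on both arrays were split by signal into 5 groups of 2764. In the dimmest group the median log2 difference was -0.27, and 6 genes were at least 2-fold higher against 296 lower. In the brightest group 0 genes were 2-fold lower, and of 7498 bright genes 3 were at least 2-fold higher (SALL4, CSH1 and SBSN) and 8 lower. The split of 45 higher to 1251 lower became 433 to 465 with quantile normalization and 222 to 443 with cyclic loess, the latter chosen after seeing the data. There is no test for this comparison, since each side is 1 array.

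**Figure D1:**
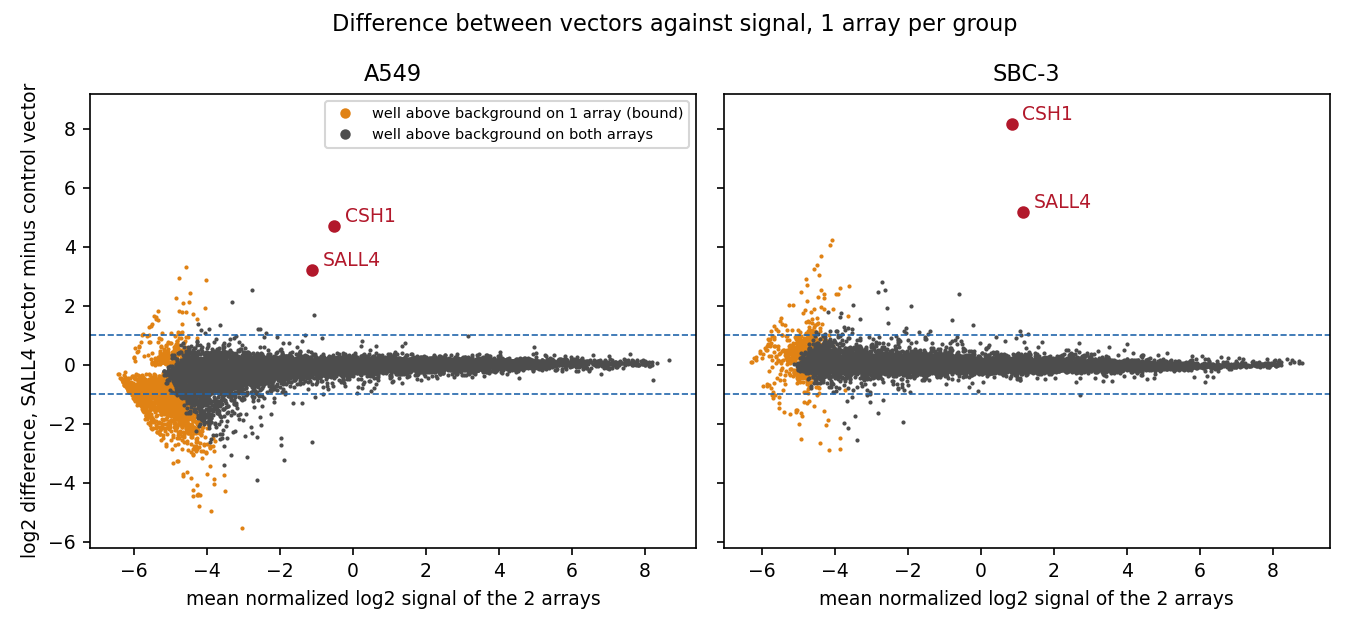
Log2 difference between the SALL4 and control vector arrays (vertical axis) against the mean normalized log2 signal of the pair (horizontal axis), for A549 and SBC-3, with 1 point per gene, bounds in orange and dashed lines at a 2-fold difference. SALL4 and CSH1 stand apart at the top in both lines, and most of the 1251 lower A549 genes lie at the dim end.

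Gene lists fixed before the data were examined showed small differences in A549. For each list the median log2 difference was placed among 10000 random lists of the same size and signal, as a description of these 2 arrays, and 12 of the 25 lists lay outside the central 95% of the random medians. Cholesterol and fatty acid synthesis genes were the lowest against their range, with a median of -0.17 (percentile 0.0) and 27 of 31 genes below 0. Examples are the sterol carrier gene STARD4 (-0.52) and the lipid regulator SREBF1 (-0.44). NF-kB and inflammatory genes had a median of 0.15 (percentile 100) with 13 of 16 above 0, among them the apoptosis inhibitor BIRC3 (0.39), the chemokine CXCL5 (0.36) and the NF-kB inhibitor TNFAIP3 (0.29). PTGS2 (-0.68) and CCL5 (-0.79, a bound) went the other way. Heat shock genes had a median of 0.16 (percentile 100) with 14 of 18 above 0. Among them were HSPH1 (0.29), CRYAB (0.25, a bound) and BAG3 (0.24), while HSPA1L was at -0.61. The p53 targets had a median of 0.077 (percentile 99.6) with 17 of 28 above 0, including the death receptor gene FAS (0.22), but TP53INP1 stood at -0.56. Immediate early genes had a median of 0.063 (percentile 98.3) with 15 of 29 above 0, and of -0.031 with no filter on dim probes. FOSL1 and the transcription factor SRF were both at 0.45, against FOS at -0.70, JUNB at -0.65 and FOSB at -1.44, a bound. The type I interferon list had a median of 0.0034 (percentile 98.4) with 16 of 32 above 0, and of -0.017 in the deposited value table. Its median and mean differed in sign, with ISG15 at 0.36 and IRF9 at 0.47 but XAF1 at least 13.3-fold lower. The median and mean also differed in sign for the p53, immediate early, BCL2 family and SALL4 partner lists.

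Other lists lay at the low side in A549. Replication-dependent histones had a median of -0.048 (percentile 0.05) with 21 of 30 below 0, and the linker histone genes H1-5 (4.35-fold) and H1-1 (at least 2.53-fold) were lower. The NRF2 and glutathione list had a median of -0.013 (percentile 0.2), with 17 of 32 below 0 and GPX2 furthest at -0.31. Its median took the opposite sign with normexp, median scaling and cyclic loess. The epithelial to mesenchymal transition list had a median of -0.10 (percentile 0.82) with 17 of 29 below 0. Its transcription factor ZEB2 was 5.74-fold lower, and the list's median was 0.0015 with cyclic loess. Unfolded protein and integrated stress genes had a median of -0.031 (percentile 1.23) with 15 of 26 below 0, CHAC1 furthest, and 0.01 with median scaling. Lung epithelial and adenocarcinoma markers had a median of -0.14 (percentile 1.82) with 20 of 27 below 0. Of these the surfactant genes SFTPD (2.42-fold) and SFTPB (at least 2.15-fold), the water channel gene AQP4 (at least 7.66-fold) and HNF4A (at least 3.10-fold) were lower. Wnt targets had a median of -0.15 (percentile 2.2) with 11 of 14 below 0, including DKK4 (at least 6.71-fold lower) and TCF7L2 (2.27-fold lower).

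The remaining 13 lists stayed within their random range in A549. ABC drug efflux transporters had a median of -0.12 with 12 of 15 below 0. ABCB1, which encodes P-glycoprotein, was at least 2.31-fold lower, ABCB5 at least 2.74-fold and the cholesterol exporter ABCG1 2.24-fold. The SALL family and pluripotency list, SALL4 left out, had a median of -0.20 with 12 of 18 below 0, including CRIPTO (at least 4.68-fold lower), DPPA5 (at least 3.83-fold), GDF3 (at least 2.36-fold) and ESRRB (2.31-fold). SALL4 partners and textbook targets had a median of 0.029, with MEIS1 furthest at -0.55. Platinum transport and DNA repair genes had a median of 0.041, with the metallothionein gene MT1X furthest at 0.41. BCL2 family and apoptosis genes had a median of 0.035, with BMF at least 2.77-fold lower. Tubulins and microtubule proteins had a median of -0.0079, hypoxia and glycolysis genes 0.025, and cell cycle genes 0.062. MAP2 (-0.96, a bound), ALDOC (-0.67) and MKI67 (-0.27) were their furthest members. Cancer stem cell markers had a median of -0.018, with the Notch target HES1 2.57-fold lower. Neuroendocrine markers had a median of -0.13, with CALCA 2.45-fold and SYP at least 2.14-fold lower. Among markers of other cell types, fibroblast markers had a median of -0.21 over 6 genes, blood cell markers -0.23 over 10 and endothelial markers -0.45 over 4, and 1 gene of each (COL1A1, CD3E and PECAM1) was at least 2-fold lower. None of the list members named here as at least 2-fold lower in A549 was among the bright genes, and dim A549 genes were lower in general.

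The same comparison in SBC-3 gave more genes higher than lower. The CSH1 probe read 286-fold higher (log2 8.16 ± 0.23), while the other CSH1 probe, not well above background on either SBC-3 array, differed by 0.19. TAGLN, the actin-binding protein transgelin, was 5.28-fold higher (log2 2.40 ± 0.21), with a log2 difference of 2.58 on its other probe. EMP1, an epithelial membrane protein, was 2.88-fold higher (1.53 ± 0.21). The cytokine gene IL32 was 2.53-fold higher (1.34 ± 0.20, other probe 1.23), and the ERK phosphatase gene DUSP6 2.23-fold (1.16 ± 0.20). SAT1, the polyamine acetyltransferase, was 2.08-fold and the metalloprotease gene MMP24 2.02-fold higher. CRYAB, a small heat shock protein, was 1.86-fold and the cytokine gene IL11 1.75-fold higher (log2 0.80). TMEM151B was higher by 0.94 on the log2 scale on 1 probe and 0.11 on its other.

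Bright genes lower with the SALL4 vector in SBC-3 differed less. The LIM homeobox gene LHX3 was 2.02-fold lower (log2 -1.01 ± 0.20) on its only probe above background. The inflammatory caspase gene CASP4 was 1.44-fold lower and the chemokine receptor gene CCR7 1.46-fold lower. CRBN, the ubiquitin ligase receptor cereblon, was 1.53-fold lower and OSGEPL1 1.67-fold. The histone gene H2AC20 and the pseudogene RPL13AP3 were both 1.51-fold lower. For 3 genes the probes disagreed. C9orf40 read -0.89 and -0.15 on its 2 probes, FBRSL1 -0.55 and -0.06, and SYNE1, at -0.59 on its brightest probe, read 0.052 as the mean over its 3 probes.

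Of the 13493 SBC-3 genes compared, 110 were at least 2-fold higher and 39 at least 2-fold lower, of which 72 and 27 were bounds. Among 6667 bright genes, 8 were at least 2-fold higher, namely SALL4, CSH1, TAGLN, EMP1, IL32, DUSP6, SAT1 and MMP24, and 1 was lower, LHX3. The split of 110 to 39 became 68 to 44 with quantile normalization and 94 to 67 with cyclic loess. Probes without a gene symbol split in the same way as the named genes, 68 higher and 1982 lower of 9785 in A549 and 129 higher and 59 lower of 6887 in SBC-3.

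In SBC-3, 9 of the 25 lists lay outside their random range. Immediate early genes had the highest percentile (100), with a median of 0.18 and 24 of 30 above 0. Besides DUSP6 these were led by IER3 (0.87), EGR1 (0.61), the connective tissue growth factor gene CCN2 (0.44) and JUNB (0.40). NF-kB and inflammatory genes had a median of 0.19 (percentile 99.99) with 13 of 17 above 0, led by the cytokine genes IL6 (0.96) and LIF (0.87). TNF was higher by at least 0.66 and RELB was at 0.32. The epithelial to mesenchymal transition list had a median of 0.12 (percentile 99.9) with 12 of 21 above 0, and its members pointed both ways. S100A4 (0.84), SNAI1 (0.60) and the integrin gene ITGA5 (0.56) were higher, as were the keratin genes KRT8 (0.42) and KRT18 (0.31), while the mesenchymal transcription factor gene TWIST1 was 2.29-fold lower. Tubulins and microtubule proteins had a median of 0.056 (percentile 99.9) with 13 of 16 above 0, TUBB2A (0.70) furthest. Cancer stem cell markers had a median of 0.12 (percentile 99.2), with the intermediate filament gene NES at 0.39 and CXCR4 at 0.33. Lung epithelial markers had a median of 0.11 (percentile 98.5) with 14 of 16 above 0, SCGB3A2 (0.52) furthest. Cholesterol and fatty acid synthesis genes had a median of 0.035 (percentile 98.9) with 20 of 31 above 0, STARD4 (0.23) furthest.

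Cell cycle genes were on the low side in SBC-3, with a median of -0.073 (percentile 0.12) and 29 of 37 below 0. The replication licensing genes CDC6 (-0.39), MCM6 (-0.29) and MCM2 (-0.24) and the cyclin gene CCNE2 (-0.27) were the furthest. Histones had a median of -0.065 (percentile 0.81) with 25 of 29 below 0. The other lists lay within their range. Medians were 0.039 for ABC transporters, 0.032 for BCL2 family genes, 0.011 for the NRF2 list and 0.060 for the SALL family and pluripotency list. ABCA2 (0.27), BMF (0.86, a bound), OSGIN1 (0.35) and ESRRB (0.40) were the furthest members. SALL4 partners and textbook targets had a median of -0.037 (BMI1 0.19), platinum and DNA repair genes -0.028 (MT2A 0.32), and p53 targets -0.014 with a mean of 0.0056 (BAX 0.39). Wnt targets had a median of 0.042, and RNF43, a Wnt receptor ligase, was 2.32-fold higher. Heat shock genes had a median of 0.0077 (CRYAB 0.90), hypoxia genes 0.028 (ANGPTL4 0.45), interferon genes 0.030 (IFI44 -0.57) and unfolded protein genes -0.0086 (PPP1R15A 0.11). Neuroendocrine markers had a median of 0.13 with 7 of 7 above 0, SYP (0.57) furthest. Fibroblast markers, to which TAGLN belongs, had a median of 0.045 over 7 genes and blood cell markers 0.21 over 6. Endothelial markers had a median of 0.11 over 2 genes, too few for a percentile.

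**Figure D2:**
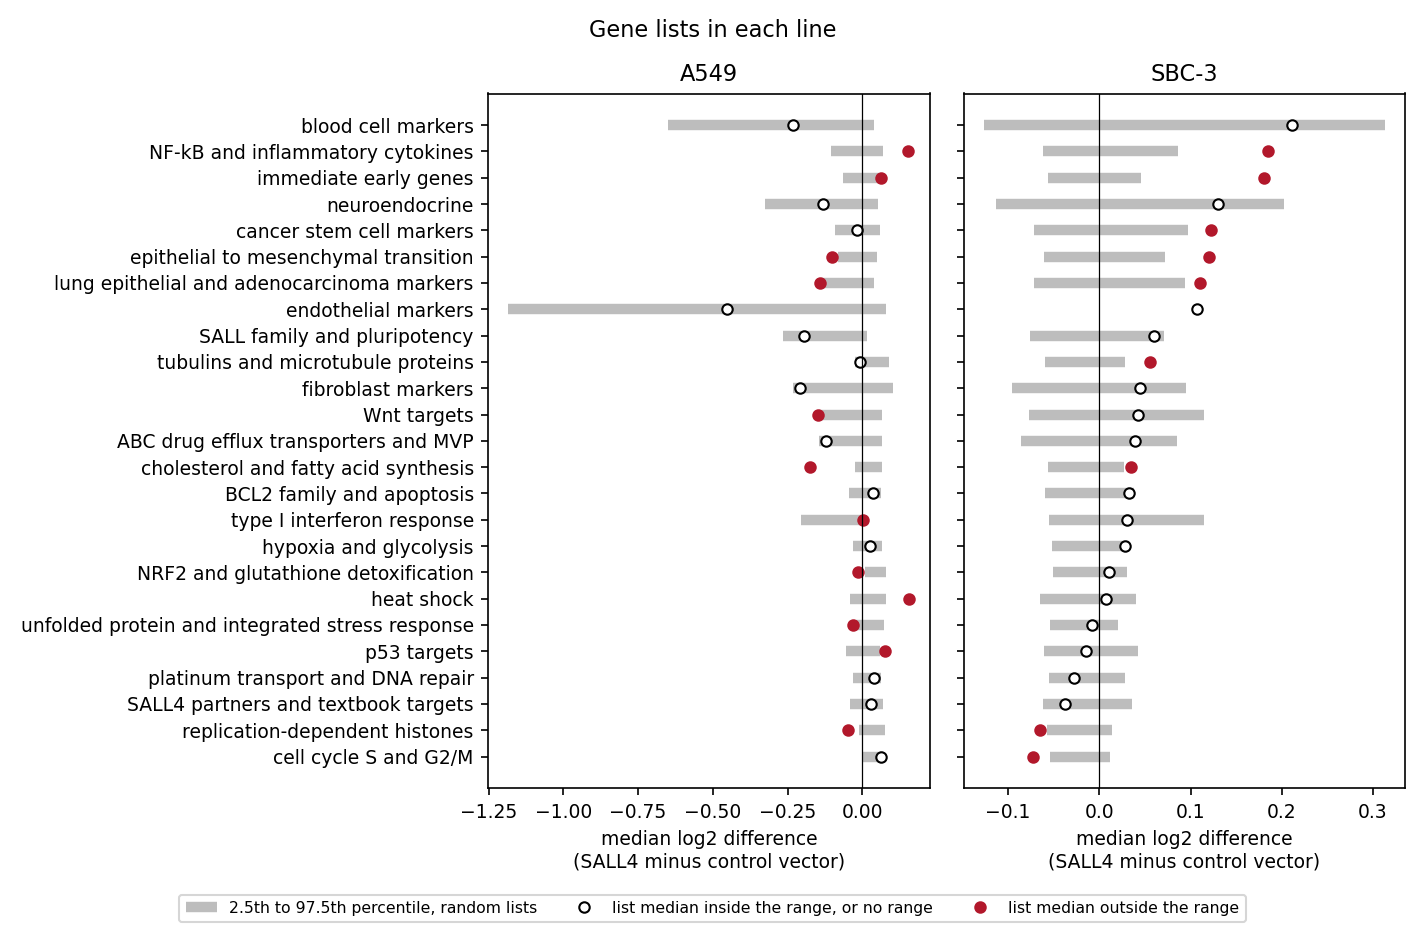
Median log2 difference (horizontal axis, SALL4 vector minus control vector) of each gene list in A549 and SBC-3, on panels with different axes, with grey bars for the central 95% of matched random lists. Red points lie outside that range, 12 lists in A549 and 9 in SBC-3, and the cholesterol list is at -0.17 in A549 and 0.035 in SBC-3.

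A further comparison joined both lines, over genes bright in each. SALL4 and CSH1 apart, the highest of these in both lines was FOSL1, an AP-1 subunit, at log2 0.45 in A549 and 0.35 in SBC-3. PHLDA2 (0.33 and 0.35) and the metallothionein genes MT2A (0.37 and 0.32) and MT1L (0.33 and 0.29) followed, with RIN1, a RAS effector (0.31 and 0.32), and TMEM158 (0.37 and 0.30). SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, stood at 0.29 and 0.40 and the neuropeptide precursor gene VGF at 0.28 and 0.51. SH3BGRL3 was at 0.28 and 0.35, but its mean over probes in A549 was -0.20. The lowest of the genes bright in both lines were KCTD19 (-0.42 and -0.32), LYRM9 (-0.25 and -0.26), VPS37D (-0.25 and -0.25), ZNF618 (-0.27 and -0.24) and the Nogo receptor gene RTN4R (-0.35 and -0.24). RBKS (-0.26 and -0.24), PLEKHG5 (-0.37 and -0.22), the readthrough gene RBAK-RBAKDN (-0.21 and -0.47), the metalloprotease gene MMP17 (-0.64 and -0.20) and ASS1, an enzyme of arginine synthesis (-0.20 and -0.32), came next. The scanner software's error of each of these differences was about 0.20. PLEKHG5 differed by 0.04 in A549 and 0.15 in SBC-3 on its other probe, which was well above background on all 4 arrays.

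In the limma fit of line and vector over all 4 arrays, which has 1 residual degree of freedom, 0 of 14626 genes passed for the vector in either direction. At an unadjusted p below 0.05, 97 genes were higher and 152 lower, and SALL4 itself had an adjusted p of 0.9999 (difference 4.19, standard error 0.62, higher in 2 of 2 lines). On simulated data with as many genes this fit recovered 0% of genes changed by 0.5, 1 or 2 on the log2 scale and 58.8% of those changed by 4. The simulated changes were the same in both lines, with a spread that did not depend on signal. In the data SALL4 differed by 3.21 in A549 and 5.17 in SBC-3, so the simulated recovery need not hold here. When the fit was restricted to 7163 bright genes, an alternative chosen after seeing the data, 2 genes rose (SALL4 and CSH1) and 3 fell (CCR7, TAC3 and DHRS3), with a smallest adjusted p of 1.61e-07 by limma. These 5 genes were named after their values were seen. CCR7 differed by -0.47 and -0.55 and DHRS3 by -0.34 and -0.70 in A549 and SBC-3, and TAC3 was above background in SBC-3 alone (-0.40).

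**Figure D3:**
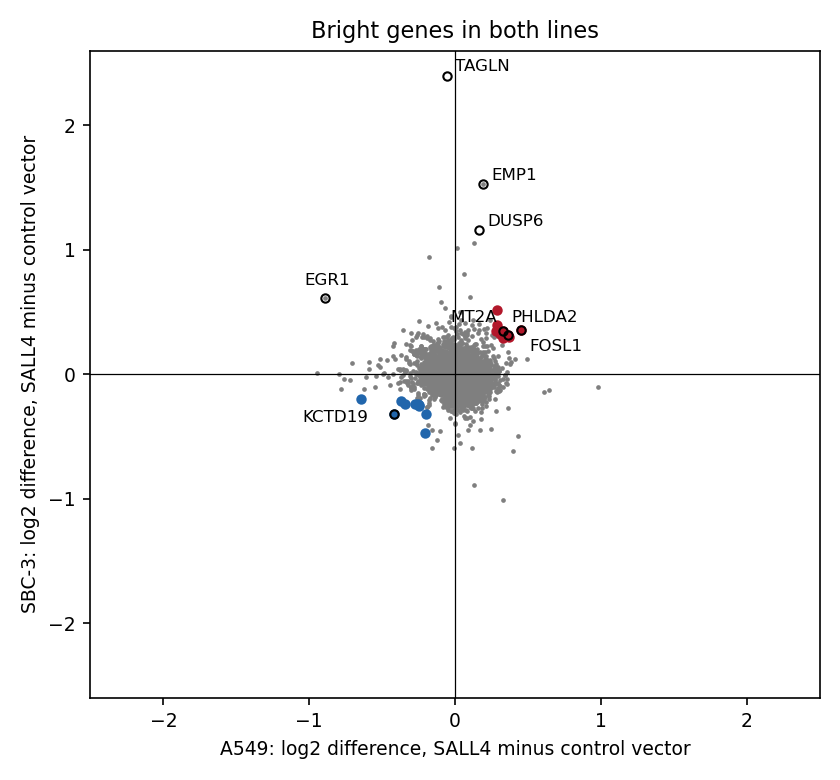
Log2 difference with the SALL4 vector in SBC-3 (vertical axis) against that in A549 (horizontal axis) for 6041 bright genes with a value in both lines, with the bright genes named as highest in both lines in red and as lowest in blue. SALL4 and CSH1 lie outside the axes, and FOSL1 is at 0.45 and 0.35.

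Across 12935 genes with a value in both lines, SALL4 left out, the differences in A549 and SBC-3 correlated with a Pearson's r of -0.170 and a Spearman's rho of -0.179. These are correlations across genes, which are not independent replicates. The differences also followed signal in opposite ways in the 2 lines. From the dimmest to the brightest of 5 signal groups, the median ran from -0.27 to 0.05 in A549 and from 0.07 to -0.02 in SBC-3. Such trends can make r negative, and r was -0.0517 with quantile normalization and -0.0564 with cyclic loess, the latter chosen after seeing the data. At least 2-fold in the same direction were 2 genes higher and 7 lower, against 0.113 and 0.746 for independent lists. In opposite directions, 19 genes were lower in A549 and higher in SBC-3, against 2.32 for independent lists, and 2 the reverse, against 0.0362. None of these 21 genes was bright in both lines. The values for independent lists treat every gene as equally likely to pass 2-fold. Among genes measured on both arrays of a line, the dimmest of 5 signal groups held 296 lower genes in A549 and 23 higher genes in SBC-3. The brightest held 0 of either, so an excess over independent lists, in the same or in opposite directions, is no evidence of a shared or opposite response. Among 6040 bright genes, an alternative chosen after seeing the data, r was 0.247 and rho -0.122. These genes included CSH1 (4.70 in A549 and 8.16 in SBC-3), which lies far from the others. A single such gene can set the sign of r, and r without CSH1 was not computed.

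By limma's camera with a preset correlation of 0.01, 5 of the 25 lists passed for the vector over both lines. NF-kB and inflammatory genes rose (median log2 difference 0.16, adjusted p = 8.53e-05), as did heat shock genes (0.080, adjusted p = 0.00641) and immediate early genes (0.056, adjusted p = 0.00641). Cholesterol and fatty acid synthesis genes (-0.063, adjusted p = 0.0296) and replication-dependent histones (-0.058, adjusted p = 0.0296) fell. None of the 5 passed with an estimated correlation (adjusted p = 0.983), and fry passed 0 lists (smallest adjusted p 0.655). Of the genes with a value in both lines, 10 of 14 NF-kB genes and 12 of 29 immediate early genes were above 0 in both, and 19 of 29 histone genes below 0 in both. Heat shock had 6 of 15 above 0 in both lines, and cholesterol synthesis 10 of 31 below 0 in both. Adjusted over the list alone, 0 genes passed in any of the 25 lists. Median and mean, or median and the camera direction, differed in sign for 7 lists that did not pass, namely pluripotency, interferon, p53, platinum, epithelial to mesenchymal transition, lung epithelial and blood cell markers.

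The last comparison set A549 against SBC-3. By limma, 4127 of 14626 genes were higher in A549 and 4891 in SBC-3, with a smallest adjusted p of 0.0019. The 10 genes furthest higher in A549 by the fitted difference were not well above background on either SBC-3 array, on the probe that represents each. That ranking uses values below background, and by bound or measured difference other genes, such as CD44 (at least 1561-fold), exceed some of them. AKR1B10 was at least 7404-fold and AKR1B15 at least 4930-fold higher in A549, S100A6 at least 5781-fold, the extracellular matrix protein gene TGFBI at least 4694-fold and the ubiquitin hydrolase gene UCHL1 at least 3605-fold. Lower bounds also held for MALL (785-fold), OCIAD2 (772-fold), the neurotrophin receptor gene NTRK3 (723-fold), the heat shock gene HSPA1A (665-fold) and PLAAT3 (653-fold). The NTRK3 bound is that of its brightest probe and not of the whole gene. A dimmer NTRK3 probe was well above background on all 4 arrays and differed less. Its normalized log2 signal was -0.36 and -0.93 in A549 and -4.03 and -3.49 in SBC-3, with the control and SALL4 vector. SBC-3 expressed several secreted peptides. The neuropeptide neurotensin (NTS) was 5683-fold higher in SBC-3, the neurokinin precursor TAC3 at least 3289-fold and endothelin 3 (EDN3) at least 881-fold. ITM2A was at least 7693-fold higher in SBC-3, SPINK6 at least 5419-fold, ZPLD1 at least 1369-fold, the BMP antagonist gene SOSTDC1 at least 1227-fold, the lipid transfer protein gene MTTP at least 695-fold and the chemokine gene PF4V1 at least 583-fold. KRT25 was at least 2579.8-fold higher in SBC-3, being well above background on 1 of the 2 A549 arrays. The adjusted p of these 20 genes lay between 0.0019 and 0.0053, each with the same direction under both vectors. SALL4 was 4.89-fold higher in SBC-3 over both vectors and did not pass (adjusted p = 0.067). This includes the SALL4 vector arrays, where it read 0.49 in A549 and 3.76 in SBC-3. On the control vector arrays it read -2.725 in A549 and -1.416 in SBC-3.

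Detoxification genes set A549 apart. Of 32 NRF2 and glutathione genes tested, 26 were higher in A549 and 2 in SBC-3, with AKR1C3 (1203-fold), AKR1C1 (1076-fold) and the efflux pump gene ABCC2 (at least 220-fold) among the highest. This list passed camera (adjusted p = 2.30e-06), as did the epithelial to mesenchymal transition list (adjusted p = 0.00893). Neither held with an estimated correlation (adjusted p = 0.884). In the latter list 16 of 29 genes were higher in A549 and 5 in SBC-3, including the epithelial keratins KRT19 (at least 814-fold) and KRT18 (548-fold) as well as TGFBI and S100A4 (205-fold). Among 14 drug efflux genes, 7 were higher in A549, led by ABCC3 (at least 476-fold) and the vault protein gene MVP (24.8-fold), and 5 in SBC-3, led by ABCB4 (at least 19.9-fold). Cancer stem cell markers had 12 of 20 higher in A549, with CD44 (at least 1561-fold) and the aldehyde dehydrogenases ALDH3A1 (619-fold) and ALDH1A1 (201-fold), and 5 in SBC-3. Lung epithelial markers had 11 of 23 higher in A549, with FOXA2 (at least 197-fold) and CEACAM6 (at least 128-fold), and 3 in SBC-3. Of 12 neuroendocrine markers tested, 7 were higher in A549, including UCHL1, DDC (at least 10.7-fold) and CHGA (at least 10.3-fold), and 2 in SBC-3, including SOX2 (75.1-fold).

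In the pluripotency list and the unfolded protein and integrated stress list, more genes were higher in SBC-3 than in A549. Neither list passed camera (adjusted p = 0.212 and 0.0904). Of 16 genes of the SALL family and pluripotency list, 8 were higher in SBC-3, among them the RNA-binding LIN28A (at least 78.7-fold) and LIN28B (33.1-fold), and 3 in A549. Histones had 14 of 29 higher in SBC-3 and 2 in A549. Unfolded protein and integrated stress genes had 17 of 26 higher in SBC-3 and 3 in A549, with SESN2 (9.71-fold) and the serine synthesis gene PHGDH (9.05-fold). Cell cycle genes had 13 of 37 higher in SBC-3 and 6 in A549, and SALL4 partners 10 of 22 against 6. NF-kB genes had 9 of 16 higher in SBC-3, with CXCL8 (127-fold), and 4 in A549, with CCL2 (at least 77.7-fold, well above background on 1 of the 2 SBC-3 arrays). Interferon genes were split, with 17 of 29 higher in A549, including ISG20 (40.1-fold), and 8 in SBC-3, including IFIT1 (75.9-fold). The counts higher in A549 and in SBC-3 were 15 and 6 of 30 for hypoxia genes, 14 and 8 of 28 for p53 targets, 15 and 8 of 33 for platinum and repair genes, and 12 and 7 of 30 for BCL2 family genes. They were 12 and 10 of 31 for cholesterol synthesis, 11 and 9 of 30 for immediate early genes, 6 and 7 of 18 for heat shock, 5 and 5 of 16 for tubulins, and 4 and 6 of 15 for Wnt targets. Markers of other cell types gave 2 and 4 of 8 for fibroblasts, 3 and 0 of 7 for blood cells and 1 and 1 of 2 for endothelium. Adjusted over the list alone, counts changed by at most 3 genes per direction, for example to 26 and 3 for the NRF2 list and 16 and 8 for p53 targets. Median and mean differed in sign for cholesterol, immediate early and Wnt genes. The pair of arrays of each line differs in vector and not in culture replicate. In the additive fit, the spread behind these p-values is the disagreement between the 2 lines' vector differences, pooled over genes. It is not a spread between replicate cultures, and it may be partly technical.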

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

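The tests on the CSH1 probe and on the dim A549 genes were chosen after their results were seen.

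EGR1 went opposite ways in the 2 lines, at -0.89 in A549 and 0.61 in SBC-3 on the log2 scale, and the difference between the lines was not tested. The median of the cholesterol and fatty acid synthesis list was -0.17 in A549 and 0.035 in SBC-3, each outside its random range, and that difference was not tested either. The same holds for epithelial to mesenchymal transition genes (-0.10 and 0.12, with 0.0015 in A549 under cyclic loess) and for lung epithelial markers (-0.14 and 0.11). Among probes without a gene symbol, which enter no comparison of genes, 3 were at least 2-fold higher with the SALL4 vector in both lines and 9 at least 2-fold lower. The probe A_33_P3303302 was higher by at least 3.19 in A549 and by 5.37 in SBC-3.

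One CSH1 probe read 26.0-fold higher in A549 and 286-fold higher in SBC-3, more than SALL4 itself and in the same order of the lines. RNA read from the SALL4 vector is a candidate explanation, since expression vectors can carry the terminator of a growth hormone gene, whose sequence resembles CSH1. Of the 6 other probes of CSH1, CSH2, CSHL1, GH1 and GH2, 0 were at least 2-fold higher in both lines, the count set for this explanation. The count cannot decide, because activation of CSH1 alone could leave it too. Where these probes lie relative to such a terminator is also unknown. Activation of the growth hormone gene cluster as a whole is argued against, because the 3 probes of CSH2, CSHL1 and GH2 well above background on both SBC-3 arrays had a median log2 difference of 0.10 (standard deviation 0.39), while activation of CSH1 alone stays open, because its other probe differed by 0.19 in SBC-3 but was not well above background there. The sequences of probe and vector were not compared, and an empty vector with the same terminator might be read as well, so the source of the signal is a hypothesis.

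Dim A549 genes were lower with the SALL4 vector, and of the 1251 A549 genes at least 2-fold lower 8 were bright. Spots well above background were 72.6% on the A549 control array, against 64.6% on the A549 SALL4 array. They were 58.4% and 60.6% on the SBC-3 control and SALL4 arrays. With 1 array per group, dim probes reading high on the A549 control array cannot be told apart from an effect of the vector. Signal that varies over the array surface is not the whole cause, since the block of spots with the fewest lower ones still had 5.17% of them, against 0.785% higher spots on the whole array. The share did vary by block up to 26.1%, 2.64 times as much as in shuffled spots (permutation p 0.001, the smallest 1000 shuffles can give), so it may add to the pattern. Such variation was not particular to lower A549 spots. The same ratio was 2.03 for higher A549 spots, 2.12 for lower SBC-3 spots and 2.16 for higher SBC-3 spots. With normexp in place of the software's background subtraction, 221 genes were still lower against 17 higher. Background handling as the whole cause cannot be excluded by this. Normexp used the local background of the same scans, and the software's well-above-background flags were kept. Of the 221 lower genes, 167 were bounds set by those flags. Lower RNA of these genes in the A549 cells stays open, although olfactory receptor genes, tied to the nose, were 2-fold lower 2.3 times as often as other genes of their signal (52.3% against 22.7%), since genes so near the detection floor exclude nothing and the line has 1 array per vector.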

How the results depend on the processing

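Cyclic loess, the fit on bright genes alone and the line fit without the A549 control array were chosen after seeing the data. In A549 the 45 higher and 1251 lower genes became 17 and 221 with normexp, 433 and 465 with quantile normalization, 197 and 2833 with no filter, 14 and 324 with genes well above background on both arrays, 222 and 443 with cyclic loess, and 3 and 8 among bright genes. In SBC-3 the 110 higher genes became 37 with normexp, 68 with quantile normalization, 770 with no filter, 38 with the stricter filter and 8 among bright genes. The 39 lower genes became 9, 188, 12 and 1 with normexp, no filter, the stricter filter and bright genes, and 67 with cyclic loess. Pearson's r between the lines was -0.0517 with quantile normalization, -0.0874 with the stricter filter and -0.0564 with cyclic loess. Among bright genes it was 0.247, a reversed sign with the far-lying CSH1 included. Spearman's rho was -0.115 with quantile normalization and -0.114 with cyclic loess. The 9 genes past 2-fold in the same direction became 1 with normexp, 82 with no filter, 2 with the stricter filter, 5 with cyclic loess and 1 among bright genes, and the 21 in opposite directions 1, 332 and 2 with the first 3 of these, 13 with quantile normalization and 0 among bright genes. For the vector over both lines the limma fit passed 0 genes under every alternative set before the data were examined, including no replicate block (4 higher and 12 lower at an unadjusted p below 0.05), where the pairing by line is dropped, and passed 2 higher and 3 lower among bright genes. Between the lines, genes higher in A549 numbered 2319 among bright genes, with fewer tested, and genes higher in SBC-3 numbered 2869 with no filter. Without the A549 control array they were 4120 and 5378. Lists past camera for the vector were 2 with no filter, 0 with an estimated correlation and 0 by fry. Between the lines they were 1 with the stricter filter, 0 with an estimated correlation and 17 by fry, which does not compare a list with other genes. In A549 the NRF2 median reversed to 0.003 with normexp, 0.0275 with median scaling and 0.0076 with cyclic loess, the epithelial to mesenchymal median to 0.0015 with cyclic loess, and the unfolded protein median to 0.01 with median scaling. The immediate early median there was -0.0308 with no filter and also with the mean over probes, and the interferon median -0.0377 with normexp, -0.0415 with no filter and -0.017 with the deposited table. With the mean over probes, SYNE1 in SBC-3 was 0.0519 and SH3BGRL3 in A549 -0.205. Filters change which genes are counted, normexp with its offset shrinks dim differences by construction, and for the other changes the cause was not tested. Of the remaining values, each for 1 gene or list under 1 alternative, 801 of named genes were the same and 36 moved in size. For lists, 350 were the same, 80 moved and 8 were weaker. For most vector differences of genes, the same means within the scanner software's error. The deposited table and median scaling shift whole arrays, and the filters keep the measured values, so many of these values could hardly move. The slide block was not run, as all arrays share 1 slide, and each line alone gives values with no test. The A549 counts cannot be had without the A549 control array, its only control. Signal over background limits the dim genes, where a 2-fold difference is often a bound.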

Other observations

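The metallothionein test and the choice of the ERK pathway were made after the values that prompted them were seen, while the further ERK targets and the cyclic loess test were fixed before their results.

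Most genes of the metallothionein family, whose coding members encode small proteins that bind zinc and copper, were above 0 with the SALL4 vector in both lines. Not all members counted are coding, MT1L being read from a non-coding transcript. Whether each probe reads its own member alone was not checked, so the counts may not be of separate genes. In SBC-3, 8 of 8 metallothionein genes with a value were above 0, with a median log2 difference of 0.17 and a highest of 0.32. In A549 it was 8 of 10, with a median of 0.32, and the exceptions were MT1IP (-1.08, a bound) and MT1DP (-0.04), which were dim. Both medians lay at percentile 100 of matched random lists. Over normexp, quantile normalization, median scaling, cyclic loess, the mean over probes and the deposited table, the medians stayed between 0.26 and 0.36 in A549 and between 0.15 and 0.23 in SBC-3. The list was gathered after MT2A and MT1L were seen among the genes highest in both lines, so the percentiles describe the family and are no independent test.

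Immediate early genes stood at percentile 100 in SBC-3, with DUSP6, IER3, EGR1 and SPRY2 among the highest. A shift shared by genes of the same signal would not give this, since the random lists were matched on signal. For that reason the percentile of 100 with cyclic loess too is no separate test of scaling that ignores signal-dependent differences. Higher output of the ERK pathway may be a cause. Of 5 further ERK target genes, PHLDA1, EPHA2, ETV4 and ETV5 had a value in SBC-3, and their median of 0.13 lay at percentile 95.15, inside the central 95% of random lists but above their median, so the explanation stays open. In A549 the 5 genes lay at percentile 89.7, and with 1 array per vector a difference between cultures cannot be told apart from one due to SALL4.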
